A study of Mus musculus with 9 samples.

How the data were processed

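The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of mouse pancreatic endocrine cell lines with an antibody against trimethylated lysine 9 of histone H3 (H3K9me3, from Active Motif, per the labels). Groups were taken from the sample labels. They are alphaTC1 cells (a murine glucagon-producing alpha cell line) 5 days after an empty vector (n = 2), alphaTC1 cells 5 days after a short hairpin RNA against Smndc1 (n = 2), and betaTC3 cells (a murine insulin-producing beta cell line, n = 2). Each of the 3 groups also has 1 input sample, which makes 9 samples. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples.

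Libraries were prepared with NEBNext Ultra II reagents and sequenced as 50 bp single reads on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Bowtie2 2.4.1, Picard 2.19.2 and MACS2 2.2.7.1 and the genome build mm10 (GRCm38); what each program did beyond its name is not given in the sources used here. The deposited peak lists hold 1 list per library, called against the input of its group according to the peak names. Each peak carries, in MACS2's column order, the authors' score, a ratio (fold over the local background) and −log10 p-values and q-values. The fold, score and −log10 values are the authors' own. The fold was used to describe peaks, and the −log10 q-value to rank and filter peaks within a list. The stronger part of a list held the peaks with a −log10 q-value at or above the list's median, and top peaks were those with the highest. The fold of each library over its own background also entered 1 test of shearing bias, with no comparison of folds between lists. The deposited table of windows holds 1 normalised signal (coverage) value per library, made by the authors, for 17641 windows. Of these, 99.84% are 401 bp wide, 14 are assigned to 2 genes each, and 14964 genes are assigned in all. Input samples entered through the authors' peak calling and were not analysed separately.

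The deposited signal was checked for its unit. In each library all values were whole multiples of a single step within a tolerance of 0.001. They are therefore whole numbers multiplied by 1 scaling factor per library, and the whole numbers are taken here as reads. The step was 1.324 and 0.8878 for the empty-vector libraries, 1.194 and 1.398 for the knockdown libraries, and 0.7986 and 0.9516 for the betaTC3 libraries. How the authors derived the factors, and whether input reads were subtracted, is not given in the sources used here. If input reads were subtracted, a value of 0 means no more reads than the input. The read numbers, floors, folds and counting intervals below would then describe only the reads left. The values are called scaled reads. Because the file holds scaled values and not read counts, limma 3.58.1 was used on log2(scaled reads + 1) as written for that case before the data were examined. All 6 libraries entered 1 model with a mean for each group, moderated with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method over the 17641 windows, and a window was called at an adjusted p below 0.05. The computations used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, bedtools 2.31.1 and matplotlib 3.10.9.

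The libraries held 5983486 and 9224783 reads in windows for the empty vector, 4530066 and 4800860 for the knockdown, and 9924487 and 7198683 for betaTC3. A group at 0 in both libraries was compared at a floor of 3 reads per library, which is 2.40 to 4.19 scaled reads, and its fold is written as at least that value. With 1 to 3 reads in a group, the ratio is that of the reads pooled over both libraries of each group, divided by the summed inverse steps, and is given with its exact 95% counting interval. It can differ from the ratio of the group means. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

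The 3 comparisons made between the groups by limma were knockdown minus empty vector, betaTC3 minus empty vector and betaTC3 minus knockdown. The first pair shares the empty-vector libraries, so the covariance of the 2 changes was compared with its value in 100 simulated tables without a shared effect, and the controls were also split between the changes. Peak lists were compared by the Jaccard index (base pairs shared over base pairs covered by either list). An exact permutation test over all 15 pairings of the 6 libraries compared indices within and between groups. A peak gained had at least 1 bp of overlap in both libraries of one group and none in either library of the other. Whether replicate numbers pair the libraries was checked from the correlation of same-numbered deviations from the group means. These were -0.0079, 0.085 and -0.176 for the 3 pairs of groups, so the numbers were not used as pairs.

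Named windows were chosen by rule before the data were examined. The rule took, per comparison and direction, the 10 called windows with the smallest adjusted p whose libraries did not overlap between groups, or 5 by unadjusted p where none passed. They had to be assigned to a named protein-coding or long noncoding gene, with 1 window per gene. It added up to 4 called genes from each gene list, and 10 fixed genes whatever their values, among them Ins1, Ins2, Gcg, Pdx1, Mafa, Nkx6-1, Smndc1 and Atrx. The 19 gene lists were also fixed before. They cover alpha cell, beta cell and pan-endocrine identity, delta, PP and epsilon cells, acinar and duct cells, hepatic and neuronal lineages, heterochromatin machinery, splicing factors, imprinted genes and germline genes. The others are gene families, namely zinc finger, olfactory receptor, vomeronasal receptor, protocadherin, Mage and Xlr, cytochrome P450, serpin and kallikrein, and keratin genes. Lists with at least 3 windows were tested against all other windows with camera in limma at a preset correlation of 0.01, and again with a correlation estimated from the data. List medians were recomputed with values under the floor set to the floor.

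Alternatives written before the data were examined were centring each library on its median, quantile normalisation, limma without trend or with robust moderation, pseudocounts of 0.1 and 10, and only windows above the median level. Others were a fit of only the groups compared, leaving out each library, replicate number as a block, and autosomes only. Stricter peak thresholds, a reciprocal overlap of 50%, peaks merged within 1000 bp, and other settings of the list tests were also written before. Tests with edgeR 4.0.16 and DESeq2 1.42.0 on reads recovered by dividing by the step, centring of each chromosome, and a crossed replicate block were chosen after seeing the data. The tests were first run on simulated data with 50 windows changed at each fold size among 17641. The changed windows were drawn only from those above 100 scaled reads with the empty vector. The simulated reads had the same assumed spread in all windows and no shift of whole libraries. Recovery in the real comparisons can therefore differ. For knockdown minus empty vector limma recovered 14% of windows at 1.5-fold, 70% at 2-fold and 100% at 3-fold and 4-fold, with 11 of 153 calls false. For betaTC3 minus empty vector it recovered 18%, 78%, 100% and 100%, with 5 of 153 calls false.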

Results

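The data comprised 6 ChIP-seq libraries labelled H3K9me3, a mark associated with silent chromatin, 2 from alphaTC1 cells with an empty vector, 2 from alphaTC1 cells with a knockdown of Smndc1, a splicing factor related to SMN, and 2 from betaTC3 cells. Each library gave 17129 to 18748 peaks with a median width of 1129 to 1287 bp, covering 22.1 to 26.0 Mb of the mm10 (GRCm38) genome. Reads in windows ranged from 4530066 to 9924487 per library, with a median of 188 to 367 reads per window. Across windows, log2 values correlated with Pearson's r of 0.9885 between the empty-vector libraries, 0.9861 between the knockdown libraries and 0.9825 between the betaTC3 libraries. The r was 0.977 to 0.983 between empty-vector and knockdown libraries and 0.573 to 0.611 between the cell lines. Windows are not independent replicates.

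Windows of the libraries labelled H3K9me3 lay mostly at gene starts. Of the 17641 windows, 11632 (65.9%) were within 1 kb of a gene start and 3290 (18.6%) were more than 10 kb away. Ribosomal protein genes, which are expressed in all cells, had a window within 1 kb of a gene end in 77 of 84 cases (91.7%, exact 95% interval 83.6 to 96.6). Among all protein-coding genes the share was 11164 of 21900 (51.0%, 50.3 to 51.6). Olfactory receptor genes, which are silent outside sensory neurons, had one in 3 of 1110 cases (0.27%, 0.0558 to 0.788), vomeronasal receptor genes in 3 of 355 (0.845%, 0.175 to 2.45), and zinc finger genes in 317 of 424 (74.8%, 70.3 to 78.8). Gene ends stand for either end of a gene.

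The first comparison addressed which regions change after Smndc1 knockdown in alphaTC1 cells. The window at the start of Smndc1 (ENSMUSG00000025024, chromosome 19, 53389863 to 53390263) held 1374 ± 5.30 scaled reads with the empty vector, 969 ± 222 with the knockdown and 1671 ± 25.5 in betaTC3 (SD, n = 2 per group). A hairpin acts on RNA, so a chromatin window does not check the knockdown. At Gcg, the glucagon gene (chromosome 2, 62481721 to 62482121), the knockdown libraries held 386.5 ± 48.3 scaled reads and the empty-vector libraries 346 ± 7.99. Atrx, a heterochromatin remodeller, held 550.3 ± 87.4 and 778 ± 41.9. By limma none of these passed, with changes in log2 of -0.52 for Smndc1 (adjusted p = 0.128), 0.15 for Gcg (adjusted p = 0.602) and -0.51 for Atrx (adjusted p = 0.119).

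In the knockdown libraries Nkx6-1, a transcription factor of beta cells, held 825 ± 180 scaled reads against 1099 ± 43.0 (adjusted p = 0.147 by limma). The beta cell genes Ins1, Pdx1 and Mafa were at 0 in both knockdown libraries and at 0.662 ± 0.936, 2.65 ± 3.74 and 5.96 ± 8.43 scaled reads with the empty vector, all near the floor of 3 reads (adjusted p = 0.308, 0.238 and 0.231 by limma). Between the alphaTC1 groups Gcg, Ins1 and Pdx1 differed by less than the larger of the SDs. The summed scaled reads were 7921856 and 8189318 with the empty vector and 5410817 and 6709387 with the knockdown. The median log2 change of all windows was -0.37, and 81.2% of windows were below 0.

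None of the 17641 windows was called between knockdown and empty vector by limma. The smallest adjusted p was 0.0641, and 6169 windows had an unadjusted p under 0.05. With edgeR and its own scaling 0 windows passed, with 2194 at an unadjusted p under 0.05, and with DESeq2 10 passed, 3 higher and 7 lower. Where libraries were centred on their medians limma called 0 windows, with 2315 (13.1%) at an unadjusted p under 0.05. The count rested on knockdown library 2, since without it 6281 windows were called, 243 higher and 6038 lower, with a single knockdown library assumed to vary like the other groups. The authors' scaling in edgeR gave 83 windows, 3 higher and 80 lower. Limma gave 163 without the trend, 335 with a pseudocount of 0.1 and 31 in a fit of only the groups compared.

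The windows closest to the threshold held few reads in either group. Sh3bp2, which encodes an adaptor protein, was at 7.08 ± 0.126 scaled reads with the knockdown and at 0 with the empty vector. Plek2, Trmt112, Enox1 and Fcrlb were at 9.47, 5.88, 5.68 and 9.36 scaled reads with the knockdown and at 0 with the empty vector, with the windows of Trmt112 and Fcrlb more than 10 kb from the gene start and that of Enox1 3032 bp away. Grn, which encodes progranulin, was at 12.2 ± 3.39 with the empty vector and at 0 with the knockdown. Kif12, Oxr1, Svil and Gadd45b were at 7.30, 7.52, 7.08 and 7.74 with the empty vector and at 0 with the knockdown, with the windows of Grn, Oxr1 and Gadd45b 1748, 4430 and 9904 bp from the gene start. None of these 10 windows passed by limma (adjusted p = 0.0641, and 0.0689 for Fcrlb). They passed without the trend and with a pseudocount of 0.1.

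No window of any of the 19 gene lists was called after knockdown by limma over all windows. Adjusted over the list alone, limma called 1 window higher and 2 lower of beta cell identity genes, 3 lower of pan-endocrine genes, 3 higher of olfactory receptors and 2 higher of cytochrome P450 genes. It also called 1 higher of hepatic genes, 1 higher and 1 lower of germline genes and 1 lower of serpin and kallikrein genes. Of the 25 beta cell windows, 12 had means below the floor of 3 reads in both groups. Those of smallest adjusted p over all windows (0.117 by limma) were at Pax4 and Pcsk1 and 148263 bp from the start of Robo1. They held at most 4.19 scaled reads in any alphaTC1 library, and the hepatic window, at Ttr, at most 2.80. As groups, 7 lists moved relative to other windows by camera at the preset correlation, and none with an estimated correlation. Only 1 of 29 windows assigned to vomeronasal receptors and 3 of 26 assigned to olfactory receptors lay within 1 kb of the gene start, and 21 and 13 lay more than 10 kb away. Windows assigned to vomeronasal receptors were higher relative to the rest, at an adjusted p of 1.24e-14 by camera in limma (adjusted p = 0.375 with an estimated correlation). With values at the floor their median log2 change was 0.35, against -0.04 in the 3121 windows of like level and -0.34 in all windows. Those assigned to olfactory receptors had a camera adjusted p of 7.16e-07 (adjusted p = 0.160 with an estimated correlation) and a median of 0.11, against -0.03 in windows of like level.

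Alpha cell identity genes (16 windows) were higher relative to the rest with a camera adjusted p of 0.00462 (adjusted p = 0.451 with an estimated correlation). Their median log2 change was -0.11 and their mean 0.03, and at the floor the median was -0.10 against -0.25 in windows of like level. Cytochrome P450 genes (camera adjusted p = 0.0113) and protocadherins (camera adjusted p = 0.0288) were also higher relative to the rest (adjusted p = 0.442 with an estimated correlation for both). Their medians were -0.16 and -0.29 and their means -0.01 and -0.12. These lay below 0, but less so than the median of all windows (-0.37), and the test compares a list with the other windows. At the floor their medians were lower than in windows of like level, at -0.16 against -0.11 for cytochrome P450 genes and -0.17 against -0.08 for protocadherins. Zinc finger genes (378 windows, camera adjusted p = 0.0113) and the heterochromatin machinery (21 windows, camera adjusted p = 0.0288) were lower (adjusted p = 0.833 with an estimated correlation for both). At the floor, the median of zinc finger genes was -0.37 against -0.40 in windows of like level, and that of the heterochromatin machinery -0.45 against -0.43. Only 2 lists passed when windows in the gene or within 1 kb of its start were used. The test did not pass for beta cell identity (camera adjusted p = 0.185), pan-endocrine (0.890), delta, PP and epsilon cell (0.162), acinar and duct (0.621), neuronal (0.965), splicing factor (0.172), imprinted (0.921), germline (0.0791), Mage and Xlr (0.288) or serpin and kallikrein genes (0.736).

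The second comparison set betaTC3 against empty-vector alphaTC1 cells, which differ in the hormone they produce. Ins1, an insulin gene (ENSMUSG00000035804, chromosome 19, 52264569 to 52264969), held 334 ± 28.1 scaled reads in betaTC3 and 0.662 ± 0.936 in alphaTC1 (SD, n = 2 per group), a ratio of 632 from the pooled reads of each group (95% counting interval 113 to 24980, adjusted p = 1.83e-05 by limma). Pdx1 and Mafa, transcription factors of beta cells, held 1835 ± 8.29 and 1498 ± 323 scaled reads in betaTC3 (adjusted p = 9.12e-05 and 0.000561 by limma). Gcg held 0 in both betaTC3 libraries, at least 132-fold lower than in alphaTC1 (adjusted p = 5.41e-06 by limma). Ins2, the other insulin gene, has no window, and a peak covered it (chromosome 7, 142678656 to 142679726) in both betaTC3 lists and in none of the 4 alphaTC1 lists.

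**Figure D1:**
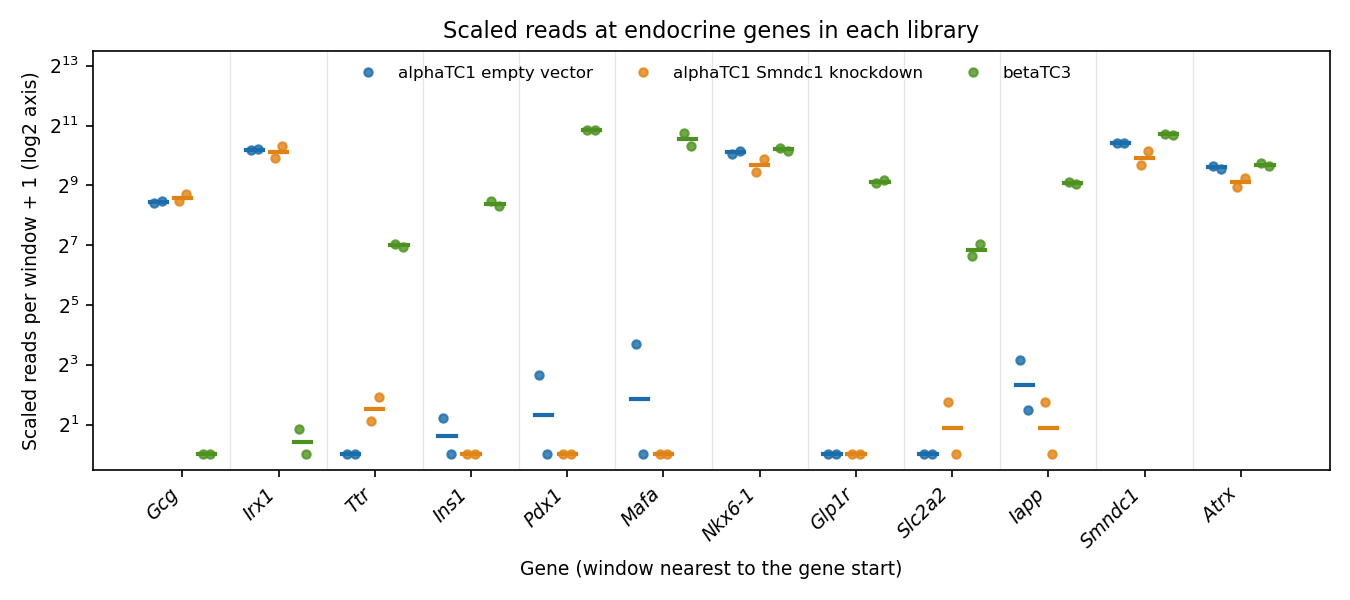
Scaled reads plus 1 on a log2 axis in the window nearest the start of each endocrine gene, Smndc1 and Atrx, with 1 point per library, bars for group means of the log2 values and colours for empty vector, knockdown and betaTC3. Ins1, Pdx1 and Mafa lie at 0 to 11.9 scaled reads in the 4 alphaTC1 libraries and far above in betaTC3, and Gcg and Irx1 the other way.

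Of the 17641 windows, 9744 were called by limma, 3893 higher and 5851 lower in betaTC3 (40.0% higher). With libraries centred on their medians 11673 were called, 51.8% of them higher, and the share was 52.0% with edgeR and 55.6% with DESeq2, so the split between directions rests on the scaling. The median log2 change of all windows was -0.13 before centring. Of the 9744 windows, 9322 were also called after centring and 9397 by edgeR. The change exceeded 3 in log2 for 2086 windows higher and 1369 lower. Among windows above the median level alone, 3034 of 8820 were called.

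The 10 windows with the smallest adjusted p among those higher in betaTC3 were at 0 in both empty-vector libraries. Gna13, which encodes a G protein subunit, held 1169.8 ± 0.253 scaled reads in betaTC3 (at least 353-fold, ENSMUSG00000020611, chromosome 11, 109363231 to 109363631, adjusted p = 5.41e-06 by limma). Gna13 lies in a run of 17 adjacent windows with at most 3 reads in each alphaTC1 library, which was noticed after the values were seen. Glp1r, the receptor of the incretin GLP-1 (ENSMUSG00000024027, chromosome 17, 30901762 to 30902162), held 554 ± 27.4 (at least 167-fold). Lhx1, a transcription factor, held 832 ± 3.44 scaled reads (at least 251-fold), and Nuak2 and Kcnip1 were at least 183-fold and at least 175-fold higher. Prune2, Ffar4 (a fatty acid receptor), Cgas (a DNA sensor), Rasgrf1 and Cadm3 were at least 149-fold, 138-fold, 133-fold, 122-fold and 121-fold higher.

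Mark1, a microtubule-related kinase, held 757 ± 51.0 scaled reads in empty-vector alphaTC1 and 0 in betaTC3 (at least 288-fold lower, adjusted p = 5.41e-06 by limma). D16Ertd472e, CT030740.1, Fam189a1 and Nell2 were also at 0 in betaTC3 and at least 337-fold, 325-fold, 280.5-fold and 174.5-fold lower. Fmnl2, a formin, and Ppp1r9a, a scaffold of actin, were lower by ratios of pooled reads of 812 (224 to 6712) and 691 (191 to 5712). Zfp641, Zfp870 and Lgr5, a receptor of R-spondins, changed by -6.93, -7.04 and -6.79 in log2.

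Nkx6-1, Atrx and Smndc1 were not called between betaTC3 and empty vector, with log2 changes of 0.10, 0.08 and 0.28 (adjusted p = 0.667, 0.671 and 0.258 by limma). With libraries centred on their medians all 3 were called, at 0.28, 0.27 and 0.46. Of the called windows within 2 kb of the start of an alpha or beta cell identity gene, 22 of 26 (84.6%) were higher in the line of the listed cell type. These were 7 of 10 for alpha cell genes and 15 of 16 for beta cell genes. The exceptions were Gc, Rfx6, Ttr and Robo1. This count was chosen after the values were seen.

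Beta cell identity genes (25 windows) were higher in 19 and lower in 3 windows, and adjusted over the list alone in 19 and 4. The list was higher relative to other windows (camera adjusted p = 2.92e-05 in limma, adjusted p = 0.220 with an estimated correlation), with a median log2 change of 5.76, or 5.10 with values at the floor. It included Pcsk1, a prohormone convertase, at 634 ± 8.36 scaled reads against 1.99 ± 0.947. A window assigned to Prlr, the prolactin receptor, but 46645 bp from the gene start, was lower at 8.12 against 253. Alpha cell identity genes (16 windows) were higher in 4 and lower in 11 (camera adjusted p = 0.154). Irx1, a homeobox gene, held 1171 ± 26.7 in alphaTC1 and 0.399 ± 0.565 in betaTC3 (ratio 2705 from pooled reads, 485 to 106900), Pou3f4 held 347 ± 8.91 and 1.75 ± 0.216, and Ttr was higher in betaTC3, at 126 ± 5.24 against 0. Pan-endocrine genes were higher in 9 and lower in 6 windows (camera adjusted p = 0.379), among them Foxa1 at 417 against 47.8 scaled reads. Delta, PP and epsilon cell genes were higher in 1 and lower in 3 (camera adjusted p = 0.743), with Sst, the somatostatin gene, at 100.1 against 1.32.

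Acinar and duct genes were lower in 6 of 7 windows and higher in 1 (camera adjusted p = 0.0257, adjusted p = 0.401 with an estimated correlation). Sox9, a transcription factor of ducts, held 573 ± 39.3 scaled reads in alphaTC1 and 4.38 ± 0.541 in betaTC3. Zinc finger genes were higher in 32 and lower in 167 of 378 windows (camera adjusted p = 0.0145, adjusted p = 0.861 with an estimated correlation), and after centring in 70 and 165. Windows assigned to olfactory receptors, mostly distant from the gene, were higher in 14 and lower in 5 cases (camera adjusted p = 0.0172, adjusted p = 0.388 with an estimated correlation). Those assigned to vomeronasal receptors, likewise distant, were higher in 14 and lower in 4 (camera adjusted p = 0.0190, adjusted p = 0.735 with an estimated correlation). Neuronal genes were higher in 2 and lower in 6 windows (camera adjusted p = 0.210), with Gad1, which makes GABA, at 1.75 ± 0.216 against 137 ± 4.45 scaled reads.

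The heterochromatin machinery was higher in 2 and lower in 6 of 21 windows (camera adjusted p = 0.461), and adjusted over the list alone in 0 and 6. Morc2a, a partner of the HUSH silencing complex, held 2294 ± 28.2 scaled reads in alphaTC1 and 1058 ± 185 in betaTC3. Its log2 change was -1.13, and it lies on chromosome 11, where the median change of windows above 100 scaled reads was -0.70. Splicing factors were lower in 4 of 23 windows and higher in none by limma (camera adjusted p = 0.908), and adjusted over the list alone 2 were lower. After centring 7 were higher and 4 lower. Sf3b1, a spliceosome component, held 1633 ± 101 and 813 ± 72.7. Imprinted genes were higher in 14 and lower in 11 windows (camera adjusted p = 0.461), with Mkrn3 at 926 ± 117 in alphaTC1 and 21.4 ± 4.72 in betaTC3. Windows assigned to germline genes, none within 1 kb of a gene start, were higher in 2 and lower in 1 (camera adjusted p = 0.379), protocadherins in 11 and 5 (0.0829), Mage and Xlr genes in 9 and 5 (0.0829), cytochrome P450 genes in 6 and 8 (0.735) and serpin and kallikrein genes in 1 and 1 (0.727). The hepatic list was higher in 1 of its 2 windows and the keratin list lower in 1 of 2, and neither was tested as a group.

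**Figure D2:**
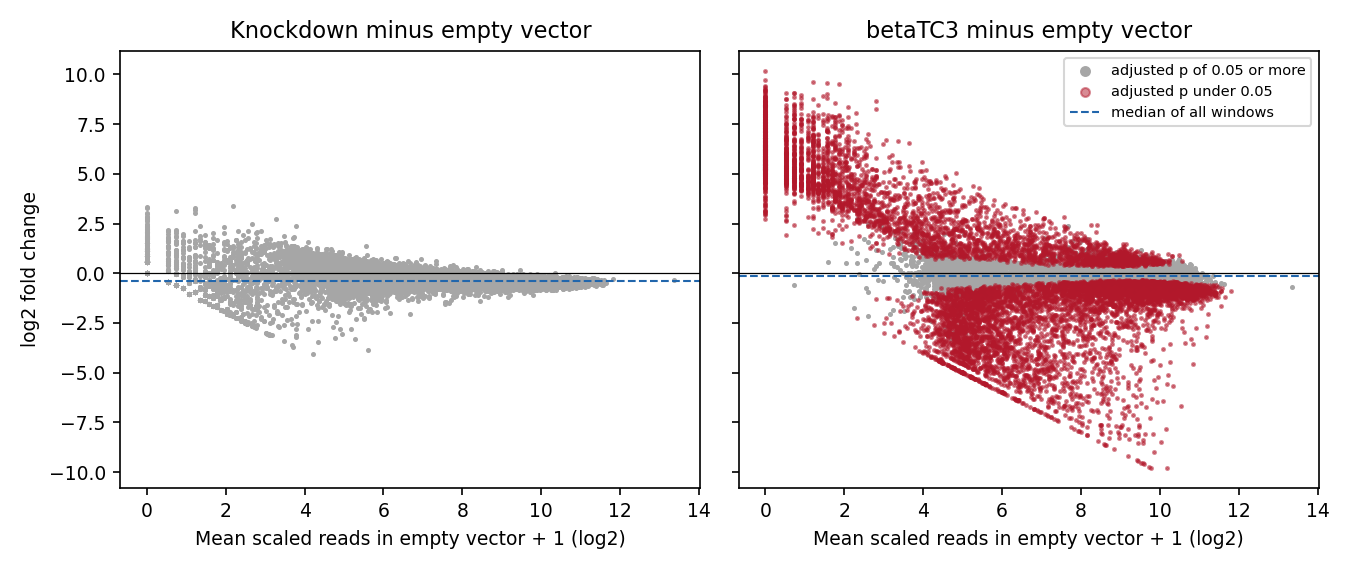
Log2 change of each window on the vertical axis against log2 of its mean scaled reads in empty vector plus 1, for knockdown and betaTC3 minus empty vector, with called windows in red and the median of all windows as a dashed line. No window was called after knockdown and 9744 were called in betaTC3.

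The chromosomes differed between the lines. Over the 9840 windows above 100 scaled reads in every library, the median log2 change of betaTC3 minus empty vector was -0.70 on chromosome 11 and 0.63 on chromosome 14. The SD of the chromosome medians was 0.32, against at most 0.0481 in 1000 permutations of windows over chromosomes, a test chosen after the medians were seen. For knockdown minus empty vector the SD was 0.0125. With each chromosome centred on its median, 10589 windows were called by limma between betaTC3 and empty vector, 52.1% of them higher. The 17 windows of the run that holds Gna13 spanned 1.56 Mb of chromosome 11 (108921161 to 110479924, from Axin2 to Gm11682). They held 16 reads in all over the 4 alphaTC1 libraries and a median of 210 scaled reads in betaTC3.

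**Figure D3:**
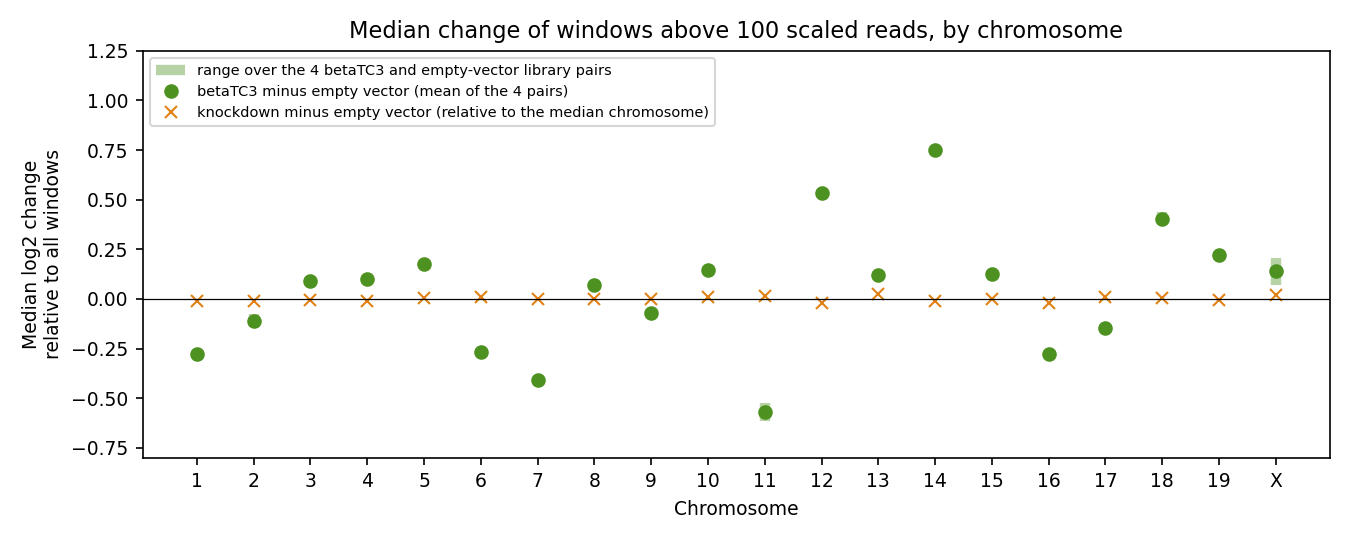
Median log2 change per chromosome, over windows above 100 scaled reads in every library. Points for betaTC3 minus empty vector are relative to all these windows and give the mean of the 4 library pairs, with bars for their range. They run from -0.57 on chromosome 11 to 0.75 on chromosome 14. Crosses for the knockdown are relative to the median chromosome and stay near 0. Before that centring the knockdown medians were -0.448 to -0.402.

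**Figure D4:**
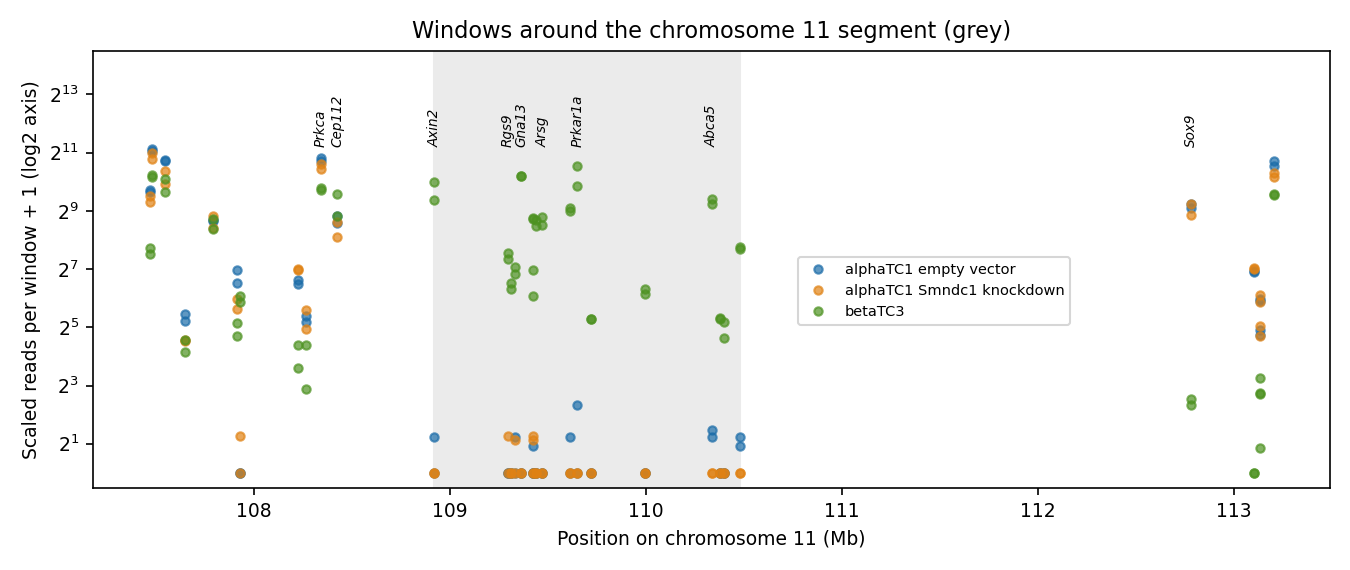
Scaled reads plus 1 on a log2 axis by position on chromosome 11 in Mb, with 1 point per window and library and the run of 17 windows in grey. In the run the 4 alphaTC1 libraries lie near 0 and the betaTC3 libraries do not.

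The third comparison set betaTC3 against knockdown alphaTC1 cells. By limma 10691 windows were called, 6451 higher and 4240 lower in betaTC3 (60.3% higher). The share of higher calls was 51.8% with libraries centred on their medians (12228 windows) and 45.7% after quantile normalisation (12142 windows), and the median log2 change of all windows was 0.23. Of the 10691, 10354 were also called after centring and 10336 by edgeR. Without betaTC3 library 1 the count was 6523, and 4264 of 8820 windows above the median level were called. Gna13, Lhx1, Nuak2, Kcnip1 and Glp1r were at least 301-fold, 214-fold, 156-fold, 149-fold and 143-fold higher in betaTC3. Galr1, a galanin receptor, held 884 ± 72.5 scaled reads in betaTC3 and 0 in knockdown cells (at least 227-fold), and Kif12, Gpr119 and Abca5 were at least 220-fold, 167-fold and 165-fold higher. Abca5 lies in the same run as Gna13.

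Gcg was at least 147-fold lower in betaTC3 than in knockdown cells, and Ins1, Pdx1 and Mafa were at least 85.9-fold, 472-fold and 385-fold higher (adjusted p = 5.7e-06, 1.39e-05, 5.36e-05 and 0.000243 by limma). D16Ertd472e, CT030740.1, Mark1, Fam189a1 and Cacna2d3, a calcium channel subunit, were at least 239-fold, 218-fold, 211-fold, 182-fold and 110-fold lower. Fmnl2 and Ppp1r9a were lower by ratios of pooled reads of 578 (159 to 4779) and 553 (153 to 4577), and Zfp641 and Lgr5 changed by -6.64 and -6.44 in log2. Smndc1, Atrx and Nkx6-1 were called higher in betaTC3 by 0.80, 0.59 and 0.53 (adjusted p = 0.0115, 0.0163 and 0.0427 by limma). Nkx6-1 was no longer called after quantile normalisation, where its change was 0.21, with chromosomes centred (0.22), without the trend, with a pseudocount of 0.1 or with the replicate block, and Atrx no longer with chromosomes centred (0.27). By camera in limma 3 lists passed, beta cell identity with 20 windows higher and 4 lower (camera adjusted p = 0.00635, adjusted p = 0.356 with an estimated correlation), alpha cell identity with 4 and 10 (camera adjusted p = 0.0190, adjusted p = 0.885 with an estimated correlation), and acinar and duct genes with 1 and 6 (camera adjusted p = 0.00768, adjusted p = 0.356 with an estimated correlation). With windows in the gene or within 1 kb of its start, 6 lists passed.

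Whether knockdown moved alphaTC1 toward betaTC3 was compared over all windows. The covariance of the knockdown change with the betaTC3 change was 0.117, against 0.0452 ± 0.00128 (SD) and at most 0.0478 in 100 simulations in which no group changed and the empty-vector libraries were shared. The difference from the simulated mean was 0.0714. With empty-vector library 1 for the knockdown change and library 2 for the betaTC3 change it was 0.00917 (covariance 0.00913, highest simulated 0.00354), and in the crossed assignment 0.122 (covariance 0.122, highest simulated 0.00377). Both lay above every simulation, and the size rested on which control was used. The simulations held neither a betaTC3 change nor a knockdown change that differs with signal level. In the data, windows of high signal changed by a median log2 of -0.448 after knockdown and windows of middle signal by -0.105. Windows with almost no reads with the empty vector can hardly fall. A covariance above these simulations therefore does not show a move toward betaTC3, with shared or split controls. Pearson's r across windows was 0.0942 with shared controls, and 0.00627 and 0.0962 with split controls. The highest simulated r was 0.524 with shared controls, and 0.0263 and 0.0278 with split controls. Only r in the crossed assignment lay above its simulations. The simulated betaTC3 change was noise alone, so simulated and observed r are not on a like footing. Windows called higher in betaTC3 had a median knockdown change of -0.16, those called lower -0.35 and the 7897 not called -0.41, so windows lower in betaTC3 fell less than windows not called. Of 394 windows higher after knockdown at an unadjusted p under 0.05, 277 were higher in betaTC3 and 35 lower, and of 5775 lower, 1932 were lower and 732 higher. Independent changes would give 86.95 and 1915 in the same direction, but both changes share the empty-vector libraries, so these medians and counts have no valid chance value. No window was called after knockdown by limma, so there was no overlap of calls to count.

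Peak lists differed more between the cell lines than between the alphaTC1 groups. The Jaccard index was 0.8823 between the empty-vector libraries, 0.8662 between the knockdown libraries and 0.8743 between the betaTC3 libraries. It averaged 0.8526 (0.8283 to 0.8695) between empty vector and knockdown, 0.6686 (0.6613 to 0.6746) between empty vector and betaTC3, and 0.6517 (0.6376 to 0.6608) between knockdown and betaTC3. Empty-vector library 2 and knockdown library 2, at 0.8695, were more alike than the knockdown libraries were. The mean within groups exceeded the mean between groups by 0.15, with a one-sided exact permutation p of 0.0667, the smallest that 15 pairings allow.

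Between alphaTC1 groups, 486 peaks were in both knockdown lists and neither empty-vector list, and 283 the reverse. The other ways of splitting the 4 lists into pairs gave 70 and 187, and 291 and 69. With presence required in the stronger part of the lists, and absence from the full lists of the other group, the counts were 0 and 0. With equal numbers of top peaks they were 288 and 243, with reciprocal overlap 785 and 753, and with merged peaks 257 and 182. The median fold of gained peaks was 4.70 in a list with a median of 24.0, and that of lost peaks 5.15 in a list with a median of 32.4. The groups were called against different inputs, which cannot be told apart from the treatment here. Between betaTC3 and empty vector 2683 peaks were gained and 2972 lost, and 157 and 102 with presence required in the stronger part of the lists. Of the 2683 peaks gained in betaTC3, 70 (2.61%) were also in both knockdown lists, and 40 (1.55%) of the 2573 gained against knockdown were in both empty-vector lists. Of the 2972 peaks lost in betaTC3, 206 (6.93%) were absent from both knockdown lists, and 357 (12.3%) of the 2893 lost against knockdown were absent from both empty-vector lists.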

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

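Tests with edgeR and DESeq2, centring of chromosomes and the crossed replicate block were chosen after the results were seen; the other alternatives were written before the data were examined. For knockdown against empty vector, where limma called 0 windows, the count was 163 without the trend, 335 with a pseudocount of 0.1, 31 with only the groups compared, 83 with edgeR at the authors' scaling and 10 with DESeq2. Leaving out a library gave 0 to 6281, the latter without knockdown library 2; leaving out any other library gave 0 by limma. For betaTC3 against empty vector, windows above the median level alone gave 3034 calls among 8820 windows tested, against 9744 among 17641, and leaving out a library gave 6983 to 10641. For betaTC3 against knockdown that filter gave 4264 and leaving out a library 6523 to 11055. The replicate block left these counts within 1.5 times. The shared-control difference of 0.0714 was 0.0451 after quantile normalisation, 0.0671 on autosomes, 0.0972 and 0.0569 without empty-vector library 1 and 2, and 0.00917 and 0.122 with split controls.

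With presence required in the stronger part of the lists, 0 peaks were gained and 0 lost after knockdown. Peaks gained numbered 288 among top peaks, 785 with reciprocal overlap and 257 after merging, against 486. Peaks lost numbered 753 with reciprocal overlap and 182 after merging, against 283. In betaTC3 the stronger part gave 157 gained and 102 lost, and merging 1955 lost. The peak overlap within groups kept its direction, with differences of 0.1322 to 0.15. Of 7, 5 and 3 gene lists past the threshold after knockdown and in betaTC3 against empty vector and knockdown, an estimated correlation left 0, 0 and 0; windows in the gene or within 1 kb of its start gave 2 after knockdown and 6 in betaTC3 against knockdown. With chromosomes centred, Gemin7 in betaTC3 against empty vector turned from -0.51 to 0.0605, and Mphosph8 and Setdb2 against knockdown from 0.94 and 0.72 to -0.137 and -0.355, since the centring removed -0.57, 1.08 and 1.08. Otherwise the cause was not tested. Of the named windows' alternatives, 777 of betaTC3 against empty vector kept their side of the threshold, 7 passed anew and 7 no longer passed; against knockdown 766 kept it and 6 no longer passed; after knockdown 151 kept it and 20 passed anew. Limma recovered 14% of 1.5-fold changes in simulated data that had no shift of whole libraries. The real knockdown libraries differed by a median log2 of 0.248. Recovery in the real comparison was not measured, and the absence of calls does not show that nothing changed.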

Other observations

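All tests below were chosen after the results were seen, except the comparison of windows near to and far from gene starts, whose bound was written before.

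The windows of these libraries labelled H3K9me3 lay at gene starts and followed gene use, unlike a mark of silent chromatin. Gene use was taken from the gene lists and families, since no expression data were used here. Of the called windows of alpha and beta cell identity genes, 84.6% were higher in the line of the listed cell type. For beta cell genes this was 15 of 16, which argues against the peaks reporting a silencing mark at these genes. For alpha cell genes it was 7 of 10, while 5851 of all 9744 called windows were higher in alphaTC1, so these genes add little. The lowest of the 6 median folds over input at gene ends was 29.1, among called peaks alone, whose folds reached down to 1.33, which argues against shearing bias that the input shares as the source of these peaks. Ribosomal protein genes had a window 40.7 percentage points more often than all protein-coding genes, as a mark of active promoters would give. A candidate explanation is therefore an antibody that bound such a mark or exchanged material, which are left open together and which no value here separates, and no biological explanation was tested.

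Both knockdown libraries held less scaled signal than the empty-vector libraries. Windows above 800 scaled reads fell more than windows of 20 to 100, by a difference in log2 of -0.513 in knockdown library 1, which argues against a wrong scaling factor alone in that library. In knockdown library 2 the difference was -0.184. Between replicates it was -0.0489 for the empty vector, -0.184 for betaTC3 and 0.32 for the knockdown (library 2 minus library 1). Since replicates reached that size, a scaling factor remains open in knockdown library 2. Lower enrichment over background may explain both. The library with the lower total had the larger difference (-0.513). Windows of high signal also weigh heavily in the total, so this match is not separate evidence for lower enrichment. A loss of the mark after knockdown has the same profile and cannot be told apart from lower enrichment. The knockdown libraries themselves differed by a median of 0.248 beside the group change of -0.37.

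The SD of chromosome medians between betaTC3 and empty vector was 0.32, above the highest of 1000 permutations (0.0481), which argues against chance scatter. Among windows with a mean above 20 scaled reads, medians within 1 kb of gene starts and more than 10 kb away were correlated over 20 chromosomes. Pearson's r was 0.879 (one-sided permutation p = 1e-05, the smallest possible) and Spearman's rho 0.829. The r passed the bound written before. Without the 2 farthest chromosomes it was 0.795, just short of that bound. Copy number differences between the lines may explain the correlation, as a hypothesis. In the run of 17 windows on chromosome 11, longer than the 7 of 1000 random orders, the 4 alphaTC1 libraries held 16 reads, while as many other windows near 0 in alphaTC1 held a median of 34, and 5 of 1000 draws were as low, down to 14. Each alphaTC1 list had a weak peak in the run that betaTC3 shared (109011570 to 109012103 in empty-vector library 1), and the bound that leaves a loss of both copies open was set after that peak was seen, so loss and joint silencing of the segment with Gna13 and Prkar1a cannot be told apart without input reads, which were not analysed here.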
